A study of Pimephales promelas with 12 samples.

How the data were processed

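Whole larvae of the fathead minnow (Pimephales promelas), a small North American fish used in aquatic toxicity testing, were exposed for 48 h to 2,4-dinitroanisole (DNAN), a constituent of insensitive munitions. Per the labels, 10 larvae were held in each of 4 beakers per treatment, 4 larvae were sampled per exposure replicate, and 200 ng of total RNA entered each labelling reaction with the dye Cy3. Arrays from 3 groups were used here: control water, 0.81 mg/L and 26.5 mg/L DNAN as measured concentrations, with 4 replicate arrays in each. The labels list further exposure concentrations, which were not analysed here. The labels speak of exposure replicates and do not say outright that each array came from its own beaker, so p-values measure the spread between these samples.

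Each array was a custom 1-colour Agilent design (number 036574) with 62372 spots, of which 61053 carried 49849 different fish probes and 1319 were control spots. Per the file headers, images were read with Agilent Feature Extraction 10.7.3.1, which gave a spot intensity on a linear scale after background subtraction and detrending within the array, and no scaling between arrays. Per the file headers, the same software also set flags for non-uniform and outlying spots, for saturation and for signal well above background, and gave the median spot and local background intensity. The deposited value table of the series holds log2 values with no stated scale. Set against the scanner files, it closely follows the log2 intensity less a value for each array, taken here as the 75th percentile. Each probe is then reduced by its median over the 12 arrays. The correlation was 0.995 or more on each array. The slope was near 1 and positive, which settles the direction, and the log scale and the centring of probes were found from the values. Correlation and slope hardly depend on the value taken off each array, so they do not settle that value. Column medians of that table were 0.04, 0.08, 0.11 and -0.01 for control arrays 1 to 4, -0.02, -0.01, -0.03 and -0.04 for the 0.81 mg/L arrays, and 0.02, 0.01, -0.04 and -0.05 for the 26.5 mg/L arrays.

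From the scanner intensities, log2 values were taken and the 75th percentile of each array was subtracted. Control spots and spots with an outlier flag were left out, which removed 0.0345% of the probe values, and the spots of a probe were averaged. A probe was tested when it was well above background on at least 4 of the 12 arrays, a probe with several spots counting when no fewer of them were above background than not. A further 4 probes were left out because flags left under 2 values in a group. This kept 36755 probes. Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend) in 1 fit over the 12 arrays with no covariate, so that the 3 groups shared an estimate of the spread. P-values were adjusted by the Benjamini-Hochberg method within each comparison, at a threshold of 0.05. Files were read with the R package data.table (version 1.17.8), and plots were drawn with matplotlib 3.10.9 under Python 3.11.15. Array-level measures were compared with exact two-sided permutation tests.

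The fit was tested on simulated data with the real probe means and spreads, in which 200 of 36615 probes were changed. Noise was drawn independently, with the same SD for a probe in all groups. The real groups differed in spread, and some real arrays deviated together, so recovery on them may differ. For 26.5 mg/L against control it called 0% of 1.5-fold, 40.5% of 2-fold and 84% of 4-fold changes. The figures were 0%, 37.5% and 85% for 0.81 mg/L against control, and 1%, 36.5% and 83% for 26.5 against 0.81 mg/L. At 4-fold, false calls made up 10.6%, 6.59% and 5.68% of the calls in those 3 comparisons, above the nominal rate.

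Probe identifiers in the files (names beginning CONTIG, SINGLET_, UF_Ppr_AF_ and UF_Ppr_AM_) matched 0 of the 64593 genes in the reference list of genes (assembly fPimPro1.hap1.1), and the files do not pair them with gene names. The 37 gene lists fixed before the data were examined, and the genes chosen in advance, were therefore not tested. Probes were named by a rule also fixed before the data were examined, applied to probes in place of genes: among probes past 0.05 whose arrays in the groups compared did not overlap, the 10 largest rises and 10 largest falls, or the 5 lowest p-values where fewer than 5 probes passed. Of these, at most 2 identifiers in each direction are printed per comparison. Where a probe was not well above background on any array of a group, its fold is taken against a floor for that group. The floor is a mean over the arrays of the group. On each array it takes the probe's own value or the lowest value among probes above background, whichever is higher. The fold sets the mean of the brighter group against it. Such a fold is not a minimum, because a probe can fail to be well above background at values above the floor. It holds for this processing only, and another background correction gave smaller folds for the printed probes with such a fold.

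The arrays lay on 8 slides and were scanned on 2 days. The second day held control arrays 2 and 4 and 0.81 mg/L array 3. Slide, scan day and replicate number were examined as blocks. Alternatives also covered quantile, median and spike-in scaling, the deposited value table, normexp background correction with an offset of 50, other filters on dim probes, other variance models, array weights, the 8 arrays of a comparison alone, leaving out each array, and other thresholds. The planned normexp correction of the mean spot signal could not be run, because the files used here give the median spot signal, which took its place. Precision is limited by the number of arrays.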

Results

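The series addresses how the constituents of the munitions formulations IMX-101 and IMX-104 act in fathead minnow larvae, and the arrays examined here cover 1 constituent, DNAN. RNA abundance was measured in whole larvae after 48 h in control water, in 0.81 mg/L DNAN or in 26.5 mg/L DNAN, with 4 arrays per group. The 75th percentile of spot intensity ranged from 517 to 830 between arrays, and 60.8% to 74.6% of probes were well above background. Saturated spots numbered 0 on each array. No difference between groups in 5 array measures passed the test (15 comparisons, lowest exact permutation p = 0.143, two-sided, Benjamini-Hochberg adjusted p = 0.952). With 4 arrays against 4 the smallest possible p is 0.0286, so a single difference could not have passed adjustment. Across probes, arrays of the same group correlated at r = 0.955 to 0.981 and arrays of different groups at r = 0.950 to 0.979. Repeated spots of a probe varied more on control arrays 3 and 1 (median SD 0.36 and 0.20 log2) than on the other arrays (0.08 to 0.14).

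The first principal component, with 23.5% of the variance, placed the 4 arrays at 26.5 mg/L apart from the other 8. Control and 0.81 mg/L arrays overlapped along it. The second component held 14.3% and spread arrays within groups, with control array 1, 0.81 mg/L array 1 and 26.5 mg/L array 4 at its upper end and control array 3 at its lower end.

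**Figure D1:**
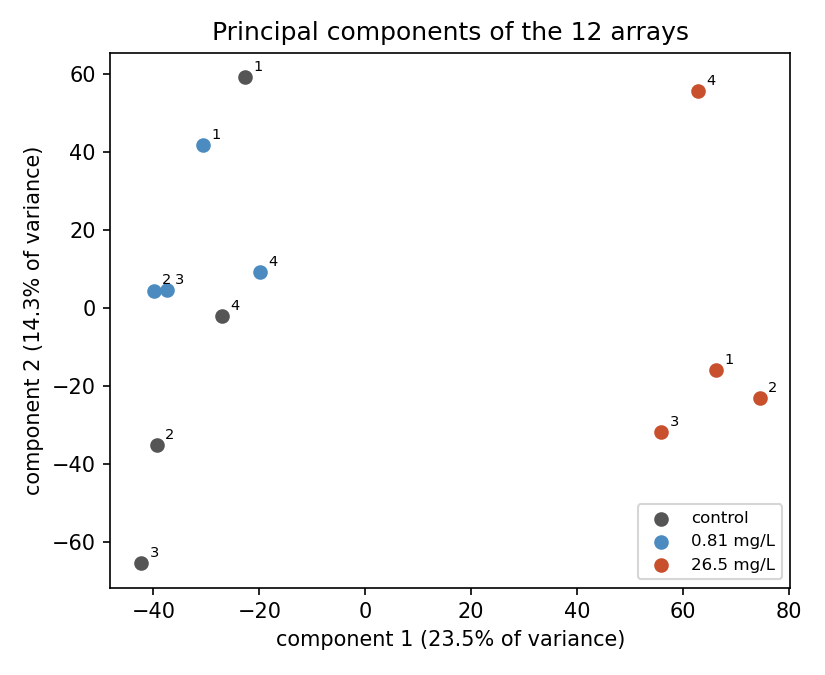
Scores of the 12 arrays on the first and second principal components (horizontal and vertical axes, percent of variance in the labels), with points coloured by group and numbered by replicate. The 26.5 mg/L arrays lie between 55.9 and 74.4 on the first component and the other 8 arrays between -42.3 and -19.9.

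The comparison of 26.5 mg/L with control asks which transcripts differ at the higher concentration. At 26.5 mg/L, 1365 probes were higher and 1750 lower than in control larvae, together 8.48% of the 36755 tested (limma, Benjamini-Hochberg adjusted p under 0.05). The median difference was 0.94 log2 among the higher probes and -0.98 log2 among the lower ones. Differences exceeded 2-fold for 609 higher and 845 lower probes, and 4-fold for 84 higher and 118 lower probes. The largest rise was that of SINGLET_33342, from -1.81 ± 0.30 in control to 3.18 ± 0.66 at 26.5 mg/L (log2 signal relative to the 75th percentile, SD, n = 4). That is a difference of 4.99 log2 (SE 0.28), or 31.7-fold, with a limma adjusted p of 2.40e-06. With normexp background correction it was 19.5-fold. It was 5.00 log2 in the deposited table (adjusted p = 0.916 with a mean-variance trend and 1.24e-05 without) and 5.46 log2 with slide as a fixed block (adjusted p = 0.119). SINGLET_33343 rose by 4.12 log2 (SE 0.36, 17.3-fold, limma adjusted p = 7.14e-05) and was well above background on 3 of the 4 control arrays. The difference was 7.19-fold with normexp, 4.13 log2 in the deposited table (adjusted p = 0.122 with a trend and 0.000186 without) and 4.25 log2 with the fixed slide block (adjusted p = 0.134). Both lay at 0.81 mg/L near their control levels, at -1.56 ± 0.24 and -3.68 ± 0.48. Among the lower probes, UF_Ppr_AF_105992 fell by 4.49 log2 (SE 0.74, limma adjusted p = 0.00312) and was well above background on 1 of the 4 arrays at 26.5 mg/L. Without that array (replicate 1) the control mean was 24.7-fold above the floor. With normexp the difference was -1.87 log2, so its size is uncertain. It was -4.48 log2 in the deposited table (adjusted p = 0.114 with a trend and 0.00543 without), -5.77 log2 with the fixed slide block (adjusted p = 0.0881) and -4.25 log2 on the first scan day (adjusted p = 0.0610). SINGLET_2243 fell by 4.23 log2 (SE 0.49, limma adjusted p = 0.000371), from 0.79 ± 0.72 to -3.44 ± 0.87, and was well above background on all 12 arrays. Its difference was -3.34 log2 with normexp, and -3.35 log2 with the fixed slide block, where it did not pass (adjusted p = 0.272). The 10 largest rises spanned 3.27 to 4.99 log2. Of the 10 largest falls, 4 were of probes well above background on at least 3 arrays of each group and spanned -4.23 to -3.29 log2, and 3 were of probes not well above background on any 26.5 mg/L array.

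Changes were called at all levels of signal. Ranked by mean signal and divided into 4 sets of near-equal size, 981 of the 9189 brightest probes changed (499 higher, 482 lower), against 406 of the 9189 dimmest (109 higher, 297 lower). By probe name, 8.74% of CONTIG, 8.30% of SINGLET_, 8.68% of UF_Ppr_AF_ and 4.85% of UF_Ppr_AM_ probes changed, the last class holding 268 tested probes. Counts of higher and lower probes depended on the scaling: median scaling gave 1589 higher and 1249 lower, and quantile normalization 1681 higher and 1568 lower. With scan day as a block 1957 probes passed, and 1068 on the arrays of the first scan day alone. The second scan day held no 26.5 mg/L array, and the only controls of the first were arrays 1 and 3, whose repeated spots varied most. With slide as a fixed block, which leaves 2 residual degrees of freedom, 1 probe passed, which was not among the 3115. As a random block, at a consensus correlation within slides of 0.0525, slide left 3105 probes. On the slide that held control array 1 and 26.5 mg/L array 3, 83.0% of the 2414 probes called from the remaining arrays had the same sign. Their median difference was 0.61 log2 on that slide, against 1.15 from the remaining arrays. Leaving out 26.5 mg/L array 2 gave 1838 probes.

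The comparison of 0.81 mg/L with control asks the same at the lower concentration. There, 0 probes passed the threshold (limma, lowest adjusted p = 0.928). At an unadjusted p under 0.05 there were 1756 probes, against 1838 given by chance. The 5 probes with the lowest unadjusted p were all lower at 0.81 mg/L, and none passed adjustment. For the 2 of them well above background on at least 3 arrays of each group the differences were -0.72 and -0.60 log2. CONTIG454 had a mean of -4.23 ± 0.68 in control and -6.57 ± 0.56 at 0.81 mg/L (SD, n = 4), where it was not well above background on any array. It was well above background on 3 of the 4 control arrays, and the control mean was 4.23-fold above the floor (limma adjusted p = 0.928). On 26.5 mg/L array 2 it was not well above background at -4.85, so that fold is not a minimum. The difference was 1.60-fold with normexp and 3.23-fold on the first scan day, so its size is uncertain. SINGLET_33407 was well above background on 1 of the 4 control arrays and on no 0.81 mg/L array (limma adjusted p = 0.928), so both groups lay for the most part at background. At this number of arrays, 200 simulated 2-fold changes gave 78 calls and recovered 37.5% of the changes. Recovery was 85% at 4-fold and 0% at 1.5-fold. The count was 0 with scan day as a block and on the first scan day alone, and 2 with slide as a fixed block. The slide with both groups held 1 array of each, and the second scan day 1 array at 0.81 mg/L and 2 controls, too few for a test of their own.

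**Figure D2:**
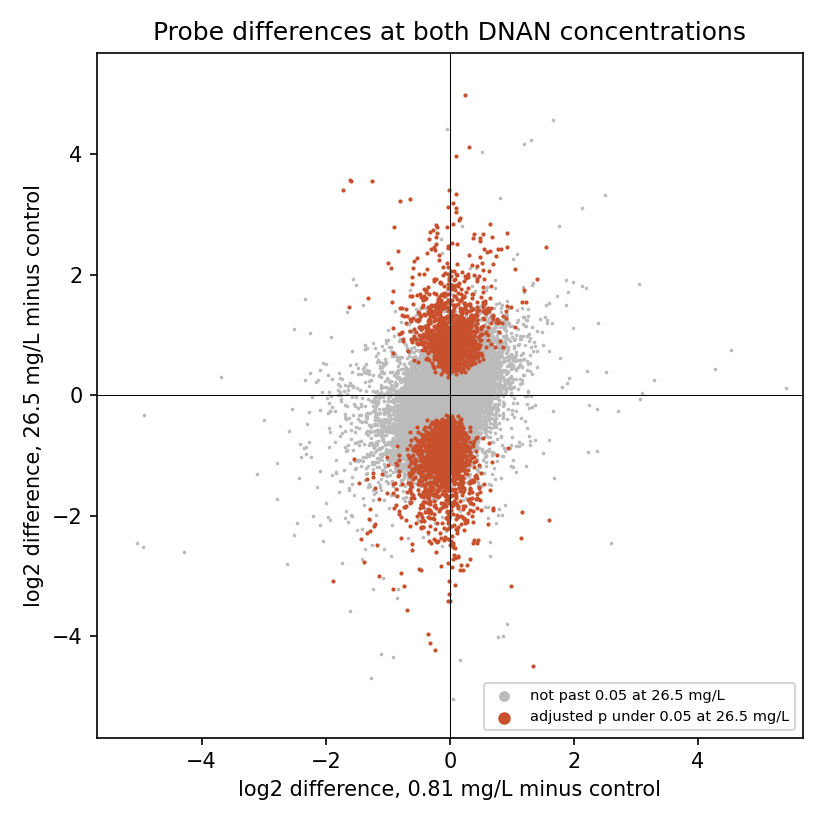
Log2 difference from control at 0.81 mg/L (horizontal axis) and at 26.5 mg/L (vertical axis) for the 36755 tested probes, 1 point each, with the 3115 probes past an adjusted p of 0.05 at 26.5 mg/L in red. Red points lie above and below the horizontal line and centre near 0 along the 0.81 mg/L axis, where the median is 0.04 log2 for the higher and -0.10 log2 for the lower probes.

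Set directly against 0.81 mg/L, the 26.5 mg/L arrays had 1515 higher and 1572 lower probes (limma, adjusted p under 0.05). The balance depended on processing, with 1006 higher and 591 lower under normexp and 1034 higher and 809 lower under spike-in scaling. UF_Ppr_AF_109937 rose from -0.28 ± 1.22 to 4.91 ± 0.27 (SD, n = 4), a 36.6-fold difference (SE 0.54 log2, limma adjusted p = 0.000134). CONTIG5672 rose by 5.14 log2 (SE 0.51, limma adjusted p = 0.000103). With the fixed slide block both differences were 22.3-fold. On control arrays 1 to 4 CONTIG5672 lay at 2.41, 0.35, 1.52 and 0.93, and UF_Ppr_AF_109937 at 2.49, 0.46, 1.52 and 0.86. Whether both report the same transcript was not tested, so counts of probes are not counts of transcripts. The control mean of UF_Ppr_AF_109937 was 1.33 ± 0.89, between those of the exposed groups. For neither probe did the difference between 0.81 mg/L and control pass the threshold. UF_Ppr_AF_105992 fell by 5.83 log2 (SE 0.74, limma adjusted p = 0.000587), with -3.01 log2 under normexp and -6.69 log2 with the fixed slide block. Without 26.5 mg/L array 1 its 0.81 mg/L mean was 62.5-fold above the floor, against 8.05-fold with normexp on all arrays. SINGLET_935 fell by 5.05 log2 (SE 1.18, limma adjusted p = 0.0201), was well above background on 1 of the 4 arrays at 26.5 mg/L, and did not pass when any of 4 single arrays was left out. Its difference was -4.41 log2 without 26.5 mg/L array 2, -2.29 log2 with normexp (adjusted p = 0.0857), -3.89 log2 with the fixed slide block (adjusted p = 0.383) and -4.95 log2 on the first scan day (adjusted p = 0.0569). On 26.5 mg/L array 3, where SINGLET_935 was above background, it lay at -1.15, near its value on 0.81 mg/L array 4 (-1.12). Without array 3 the 0.81 mg/L mean was 54.3-fold above the floor, a value that does not hold for all 4 arrays at 26.5 mg/L. SINGLET_935 was also not well above background at -3.15 and -4.40 on control arrays 1 and 3, so that fold is not a minimum. Of the 10 largest rises and 10 largest falls, 9 rises (13.9-fold to 36.6-fold) and 5 falls (-4.00 to -3.28 log2) were of probes well above background on at least 3 arrays of each group. Of the 10 in each direction, 8 rises and 5 falls were also among the 10 largest against control. With scan day as a block 2537 probes passed, 1677 on the first scan day alone and 12 with slide as a fixed block. That block left the median difference of the 3087 called probes at 0.951 log2 (0.946 without it). Its SE rose from 0.197 to 0.272 and the residual degrees of freedom fell from 9 to 2. The probes were picked on the same arrays, so that median decides nothing about slide. With slide as a random block 3158 passed. On the slide that held 0.81 mg/L array 1 and 26.5 mg/L arrays 2 and 4, 98.6% of the 716 probes called from the remaining arrays had the same sign. Their median difference was 1.42 log2 on that slide, against 1.52 from the remaining arrays. Leaving out 0.81 mg/L array 1, 2 or 3, or 26.5 mg/L array 2, gave 1805, 2017, 1966 and 1851 probes.

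**Figure D3:**
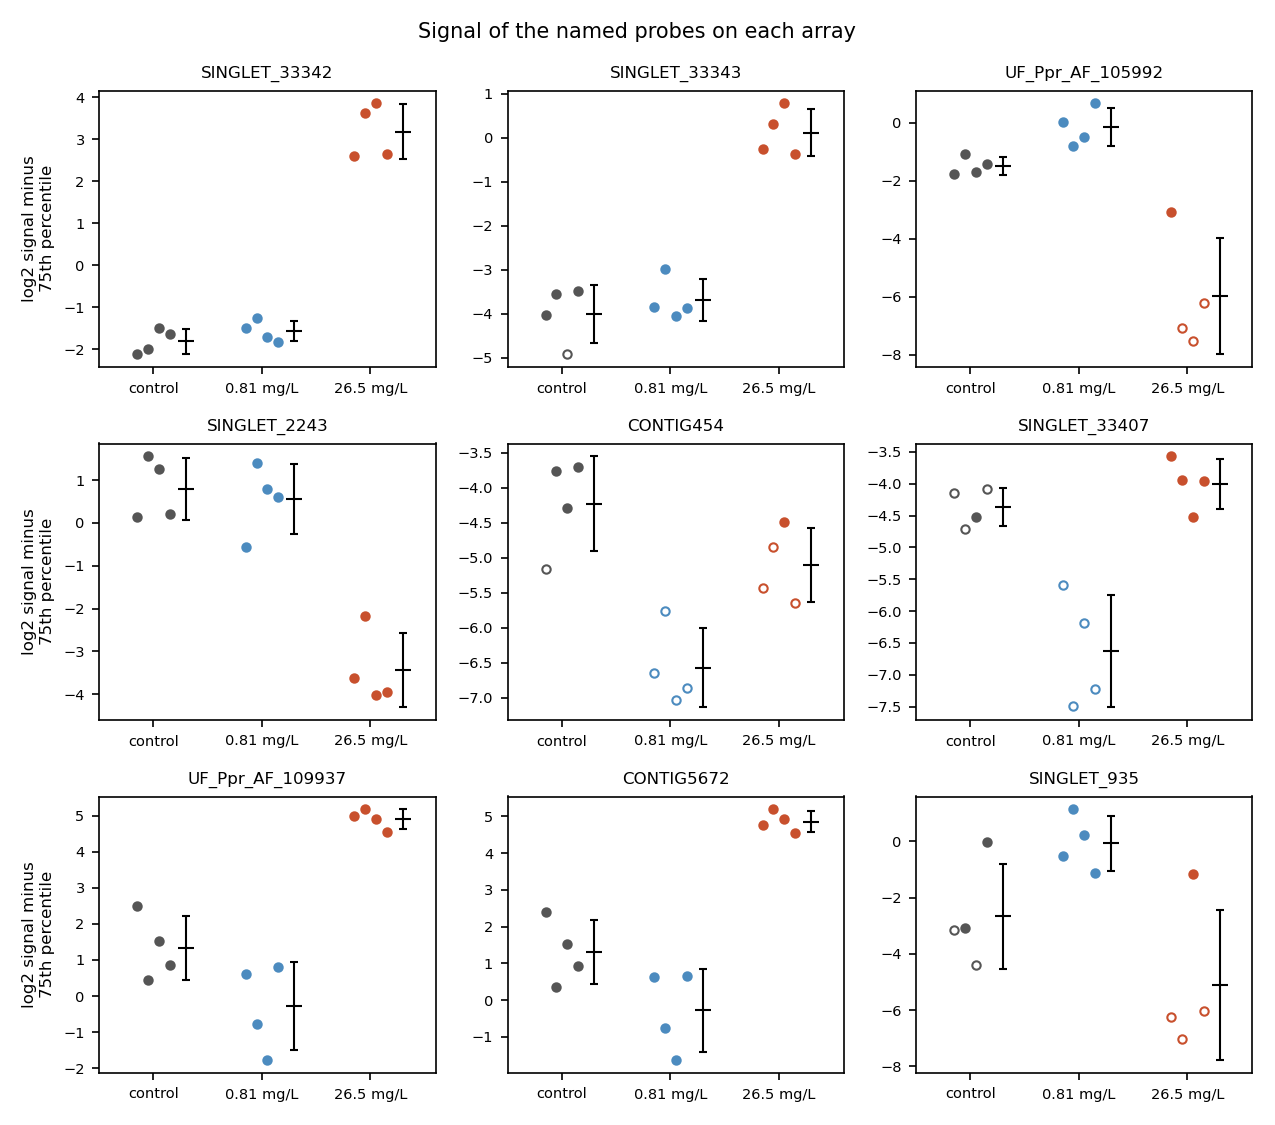
Log2 signal minus the 75th percentile of the array (vertical axes) for 9 named probes in the 3 groups, 1 point per array, with the mean and SD (n = 4) as a bar beside each group. Open points were not well above background. SINGLET_33342 lies between 2.59 and 3.86 on the 26.5 mg/L arrays and between -2.12 and -1.26 on the others.

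Of the probes called against control, 1017 higher and 1159 lower ones were also called against 0.81 mg/L in the same direction and 0 in the opposite one. Independent lists of these sizes would share 56.3 and 74.8, a value that leaves out the shared 26.5 mg/L arrays. Lists of these sizes from simulated unchanged groups with shared arrays had a median of 350 higher and 421 lower probes in common (95% range 54.2 to 680 and 58.2 to 784, 100 draws). With separate 26.5 mg/L arrays for each comparison, 2 and 2, a test added after the overlap was seen, 71 to 181 higher and 40 to 131 lower probes were called in both over the 6 halvings. Independent lists would share 2.96 to 5.07 and 2.28 to 5.98. The sign was the same for 1364 of 1365 higher and 1744 of 1750 lower probes. With the 26.5 mg/L arrays in both comparisons, simulated unchanged groups gave the same sign for 83.1% of the 3115 largest differences (95% range 58.7% to 98.0%, 100 draws).

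The relation between the responses at both concentrations was examined across probes, which are not independent replicates. The differences from control at 0.81 and 26.5 mg/L correlated at r = 0.309 (Spearman's rho 0.351). Both share the 4 control arrays, and unchanged groups simulated against shared controls gave a median r of 0.493 (95% range 0.156 to 0.730, 100 draws). The simulation held no change at 26.5 mg/L, while real changes there widen the differences and can lower r. The values 0.309 and 0.493 are therefore not like for like. The covariance is not divided by that width, and was 0.0565 against 0.0570 in the simulation (95% range 0.0119 to 0.108). With separate control arrays for each concentration, 2 and 2, the mean r over the 6 ways of halving the controls was -0.0529 (range -0.0846 to 0.0132). On the first scan day alone r was 0.488, and 0.410 with scan day as a block.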

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

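Of 42 sets of 4 arrays examined for a value far from the others (5 array measures and the 9 named probes in each group), 1 stood out, while chance gives about 1 in 20. The median spot intensity of the control arrays was 127 on array 2, and its gap to the nearest other array was 0.842 of the whole range. Array 2 was scanned on the second day, with control array 4, whose median was 82.2. Among 23 control probes above background on all arrays, no difference from the control group passed in 46 comparisons (lowest exact permutation p = 0.0571, adjusted p = 0.854), where the smallest possible p, 0.0286, could not have passed alone.

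The tests below were written before their results were seen, except that of the shift with spike-in scaling and the fit with slide as a fixed block. Of the 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many probes as the 3115 changed at 26.5 mg/L against control. The highest other split gave 1. That is the least share 35 splits can give, so it argues against chance without excluding it. The other splits put 26.5 mg/L arrays on both sides, which widens the spread, so the size of the gap adds little. An origin in slide or scan day would on average give 50% same-sign probes on the slide holding both groups, and 83.0% was found, on 1 array of each group. The median difference of those probes was 0.61 log2 on that slide, against 1.15 from the other arrays. Probes vary together and no range around 50% was computed, so how far 83.0% argues against an origin in slide or scan day is uncertain. A part owed to slide, scan day or noise therefore stays open. With slide as a fixed block, 1 probe passed, not among the 3115: the median difference of the called probes moved from 0.96 to 0.88 log2, while its SE rose from 0.20 to 0.30 and the residual degrees of freedom fell from 9 to 2. Those probes were picked and signed on the same arrays, so a large median with the block decides nothing about slide. Without control arrays 1 and 3, whose repeated spots varied most, 1858 probes passed (991 higher, 867 lower). Of these, 1545 were among the 3115, so those calls did not need arrays 1 and 3. The rest of the 3115 did not pass without them, on fewer controls. The controls left, arrays 2 and 4, were scanned on the second day and all 26.5 mg/L arrays on the first. The first scan day (1068 probes) held only control arrays 1 and 3. Neither check can therefore part those arrays from scan day. With spike-in scaling 1892 passed as the SE of the called probes rose from 0.20 to 0.23 (median), a count that could not decide the test set beforehand. The median shift of all differences was 0.00908 log2 (SE 0.11) against a median difference of 0.96 among the called probes. This argues against a common shift of the arrays as the source of the size of the differences. That shift does not address scaling that varies with signal, and how many pass stays open.

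With a count of 0 at 0.81 mg/L against control, all 35 splits of those 8 arrays necessarily gave as many, so the splits (highest other 1) weigh nothing. In simulation with independent noise 37.5% of 200 2-fold changes were recovered, with 78 calls. Changes of that size and number can thus give calls with this many arrays under such noise, while fewer or smaller ones stay open. A smaller change in the same direction as at 26.5 mg/L was tested with separate controls: on average 44.1% of the probes called at 26.5 mg/L had the same sign at 0.81 mg/L (37.7% to 55.8% over 6 halvings). The average lies under the bound of 50% set beforehand by less than the spread of the halvings, a condition applied after the value was seen, so this stays open. For 26.5 against 0.81 mg/L, 1 of 35 splits, the real one, gave as many as the 3087 probes, and the highest other gave 1.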

How the results depend on the processing

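Normexp, spike-in scaling, kept flags, the fixed slide block, the first scan day, the omission of control arrays 1 and 3 together, the deposited table without a trend and, for the correlation, scan day as a block (0.410) were chosen after seeing the data. For 26.5 mg/L against control (3115 probes) the count moved by over 1.5 times with scan day as a block (1957), the 8 arrays alone (1682), an adjusted p of 0.1 (4819), normexp (1602), spike-in scaling (1892), the fixed slide block (1), the first scan day (1068) and without control arrays 1 and 3 (1858). Single omissions gave 1838 (26.5 mg/L array 2) to 2975. For 26.5 against 0.81 mg/L (3087) it moved with array weights (4822), normexp (1597), spike-in scaling (1843), the fixed slide block (12) and the first scan day (1677), and single omissions gave 1805 (0.81 mg/L array 1) to 3629. With that slide block the median difference of the 3087 probes was 0.951 log2, against 0.946 without it, on the arrays that picked them. Omissions, the 8 arrays alone and the fixed block leave fewer arrays or residual degrees of freedom. For 26.5 against 0.81 mg/L, the 8 arrays alone gave 3831 probes, so that loss need not lower a count. The main fit shared 1 estimate of the spread over all groups. The median SD within groups was 0.34 log2 in control, 0.22 at 0.81 mg/L and 0.28 at 26.5 mg/L. P-values of 26.5 mg/L against control may therefore be too small in the main fit. For the other settings the cause was not tested. Higher probes were 43.8% of calls against control, and 56.0% with median scaling. Against 0.81 mg/L they were 49.1%, and 63.0% with normexp (1006 higher, 591 lower), which moved the median of all probes at 0.81 mg/L against control to -0.12 log2.

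At 0.81 mg/L against control, single omissions gave 0 to 1 (SINGLET_42835 without control array 2, limma adjusted p = 0.0355) and the fixed slide block 2 (SINGLET_46085 and SINGLET_10535), named after their values were seen. Other settings gave 0. The replicate block gave 2321, 0 and 2307 probes. Same-numbered arrays deviated together at r = -0.0901 to 0.201, and 1 of 12 correlated best with its own number, so no pairing by number was seen. The correlation of both concentrations (r = 0.309) moved to -0.0529 with controls split 2 and 2, which share no array, and to 0.488 on the first scan day. Single omissions gave 0.253 to 0.422.

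Named probes kept their direction in each setting run, but normexp made 8 of 10 differences smaller by over 1.5 times (SINGLET_33342 4.29, SINGLET_33343 2.85, SINGLET_2243 -3.34 log2), and the fixed slide block moved 6. Calls of SINGLET_33342, SINGLET_33343, UF_Ppr_AF_105992 and SINGLET_2243 against control ended in 2, 2, 3 and 1 settings, and that of SINGLET_935 in 7. In the deposited table SINGLET_33342 had an adjusted p of 0.916 (range over settings 9.76e-07 to 0.916), because a trend over centred probes gave it a prior variance of 2881 (16.6 for SINGLET_33343 and 15.4 for UF_Ppr_AF_105992, median of all 0.0769). Normexp on the mean signal was not run, and the 37 gene lists were not tested. Of the 36755 probes, 26997 were above background on all arrays.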

Other observations

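The test of slide column was chosen after the correlations were seen. Probes well above background on each array of 1 group and on no array of the other were counted without the filter on dim probes. Such probes numbered 32 for 26.5 mg/L and 18 for control. Of the 35 splits of these 8 arrays, 8 gave 50 or more such probes, so chance is not excluded. The highest count, 346, came from setting control arrays 1 and 2 and 26.5 mg/L arrays 2 and 3 against the rest, which are the 4 arrays with the most and the 4 with the fewest probes above background, which points to a structure of the arrays whose cause was not tested. Of the 18 probes seen only in control, 15 were above background on all 0.81 mg/L arrays, and of the 32 seen only at 26.5 mg/L, 15 were above background on no 0.81 mg/L array. Between 0.81 mg/L and control such probes numbered 57 and 0, and between 26.5 and 0.81 mg/L 22 and 126. The mean share of probes above background was 72.1% at 0.81 mg/L, 67.1% in control and 68.2% at 26.5 mg/L.

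Some arrays of different groups deviated from their group means together, up to r = 0.256 across probes. As a hypothesis, position on the slide could give such pairs. The 13 cross-group pairs in the same slide column had r from -0.179 to 0.256 with a mean of 0.0374 (exact p = 0.103, one-sided, over reassignments of columns within groups), so the column stays open. No biological explanation was tested. The median SD within groups was 0.34 log2 in control, 0.22 at 0.81 mg/L and 0.28 at 26.5 mg/L.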
